A study of Mus musculus with 6 samples.

How the data were processed

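RNA was sequenced from primary aortic endothelial cells of wild-type C57BL/6 mice in 6 samples, 3 from the group infused with saline and 3 from the group infused with angiotensin II (AngII). Per the labels' protocols, messenger RNA was purified with magnetic beads and made into strand-specific libraries by the dUTP method. The authors deposited 1 table of estimated counts of reads or fragments, without scaling to library size, for 17067 genes by symbol. In it, 83.0% of the values were whole numbers and the rest had fractions, and the column totals differed between samples. Per the submitters' processing notes, HISAT2 was used with the mouse genome build mm10, without versions. The quantifier, the gene annotation, the strand setting and any filter were not given in the sources used here, so genes that overlap or share reads with a close relative are uncertain. Genes that the table did not list were not analysed here. Each of the 6 columns was matched to its sample by title, 0 columns were left unmapped, and 0 entries lacked a gene name.

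The expected counts were rounded to whole numbers, which gave totals of 21154724 to 23004780 for the saline samples and 22646065 to 25141992 for the AngII samples. Genes near 1 CPM (counts-per-million) rest on few counts at this depth, and their values are the least precise. Gene identifiers and coordinates came from GENCODE release M21 on GRCm38, the assembly that mm10 also names, which may not be the annotation the authors used. It held 16315 of the 17067 symbols, and 99.62% of the matched genes were protein coding.

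AngII was compared with saline in edgeR 4.0.16 under R 4.3.3, with TMM scaling, the default settings of filterByExpr and the quasi-likelihood F-test. The filter, with a minimum count of 10 and a minimum total of 15, kept 12277 genes. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and a gene passed below 0.05. Fold changes are AngII over saline, and values per group are the mean ± SD of TMM-scaled CPM, n = 3. The standard error of a log2 fold change was its size divided by the square root of its F statistic. The labels do not say that the replicates came from separate animals or cultures, so all p-values measure only the spread between these samples, which may be technical. The 6 pairs of replicates within a group differed by more than sampling noise, with chi-square values per degree of freedom from 2.39 to 5.86, and each was counted as a separate sample.

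The samples' groups, the tests, the processing alternatives, the rule for naming genes and 41 gene lists with 835 members were fixed before the data were examined. The lists covered pathways of endothelial cells under AngII and markers of cell types that explant cultures can hold. Lists of immediate early, mitochondrially encoded, cytosolic ribosomal protein and sex-linked genes were included as measures of sample quality. Each list with at least 5 tested members (33 lists) was tested with camera in limma 3.58.1, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera asks whether the members of a list rank higher or lower than other genes. It was repeated with a correlation estimated from the data, and fry was run beside it. Member counts are given with p-values adjusted over all tested genes and adjusted over the list alone.

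Genes were named by 3 criteria. The 10 largest rises and the 10 largest falls were taken among genes past the threshold with a mean of at least 5 CPM, groups that did not overlap and an established symbol. Up to 3 members that rose and up to 3 that fell, those with the smallest p-values, could be named from each list. A set of genes of the renin-angiotensin system, nitric oxide synthesis, adhesion, endothelial and smooth muscle identity, oxidant production and sex was to be named whenever tested. Of these, Agtr1a, Agtr1b, Agtr2 and Xist were not analysed here, while Acta2, Tagln and Cybb were below the count filter. Some genes that these criteria select are not reported here. Genes outside the rule are said to be chosen after their values were seen.

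The alternatives were median-of-ratios size factors, library totals alone, no filter beyond 1 count, at least 5 CPM in at least 3 samples, DESeq2 1.42.0, limma-voom, the replicate number as a block, and each sample left out in turn. A test against a fold change of 1.5 in place of no change, and removal of each sample's trend on transcript GC content and length, were added after seeing the data. The comparison was tested on simulated data, with counts drawn for the 12277 tested genes from the real means, spreads and library sizes. The 200 genes changed were taken from those with a mean of at least 1 CPM, so the recovered shares leave out genes below that level. The filter kept 12180 of the simulated genes. The simulated samples were independent and far fewer genes changed than passed in the real data, so the shares below need not hold there. At a 1.25-fold change edgeR recovered 77.6% of 67 genes, at 1.5-fold 94.0% of 67 and at 2-fold 98.5% of 66, and 6.74% of the 193 genes called were false.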

Results

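The series set out to compare the messenger RNA of aortic endothelial cells, the cells that line the aorta on the side of the blood, between mice infused with saline and mice infused with AngII. AngII is the peptide hormone of the renin-angiotensin system, which constricts vessels and raises blood pressure, and its infusion is a standard model of hypertension. Mice of 8 weeks carried osmotic pumps that released AngII at 1000 ng per kg of body weight per minute, or saline, for 14 days. Their aortas were then divided into 2 mm pieces and kept on Matrigel in medium with 20% fetal calf serum, and endothelial cells left the pieces from days 5 to 7. The cells were therefore cultured outside the animal between the infusion and the measurement. Each group had 3 samples, with total counts of 21154724, 21954711 and 23004780 for saline replicates 1 to 3 and 23825548, 22646065 and 25141992 for AngII replicates 1 to 3.

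Cells from AngII-infused mice carried more transcripts of the unfolded protein and integrated stress response, of cholesterol synthesis, of the interferon response, of immediate early genes, of extracellular matrix and of angiogenic sprouting, and fewer transcripts of p53 target genes, antioxidant genes and targets of YAP and TEAD, by camera with a preset correlation between genes. With a correlation estimated from the data, 0 of the 33 lists tested passed. All 22 tested members of the unfolded protein and integrated stress response list rose, with a median of 1.84-fold. Sparcl1, which encodes a secreted matrix glycoprotein, rose the most among the genes eligible for naming, from 25.4 ± 0.591 to 114 ± 19.1 CPM (mean ± SD, n = 3). Ces2f, which encodes a carboxylesterase, fell the most among them, from 21.3 ± 1.34 to 1.45 ± 0.177 CPM (n = 3). Most changes were smaller than these, and the median absolute log2 fold change of the genes that passed was 0.29.

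Of 12277 tested genes, 3555 were higher and 3517 were lower with AngII by edgeR's quasi-likelihood test, together 57.6% of those tested. A change of at least 2-fold was found in 482 of them, 163 higher and 319 lower, while 3926 (55.5% of those that passed) had an absolute log2 fold change below 0.32. The samples of the groups did not overlap in 62.7% of genes (3846 higher, 3853 lower), where chance gives 10%. The common biological coefficient of variation was 3.19%. Of the 33 gene lists tested, 9 passed camera with the preset correlation, 6 upward and 3 downward, and 0 passed with an estimated correlation, where 3 had an unadjusted p under 0.05, while fry called 22. On the leading principal component, which held 70.8% of the variance, saline samples lay between -25.05 and -23.84 and AngII samples between 23.12 and 25.35. Mitochondrially encoded transcripts made up 4.48% to 4.61% of the counts in saline samples and 4.03% to 4.29% in AngII samples.

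Among the 10 eligible genes with the largest rises, Sparcl1 (chromosome 5, 104079111 to 104113733, GRCm38) was 4.48-fold higher, with a log2 fold change of 2.16 ± 0.0891 (SE; edgeR adjusted p = 6.4e-13). Prg2, which encodes a granule protein of eosinophils, rose by 2.15 on the log2 scale, Mmp13, a collagenase, by 2.11, and Slc7a11, the cystine and glutamate exchanger, by 1.99. Dll4, the Notch ligand of arterial and tip endothelial cells, rose from 16.6 ± 1.07 to 60.3 ± 9.59 CPM, a 3.61-fold difference (n = 3; edgeR adjusted p = 6.7e-12). Aldh1l2, a mitochondrial enzyme of folate metabolism, rose by 1.82, and Gpihbp1, which carries lipoprotein lipase across the endothelium, by 1.66. Plek rose by 1.61, and the transcription factor Egr1 and the secreted ribonuclease Rnase1 were each 3.03-fold higher.

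Among the 10 eligible genes with the largest falls, Ces2f (chromosome 8, 104947356 to 104960047) was 14.5-fold lower, with a log2 fold change of -3.86 ± 0.109 (SE; edgeR adjusted p = 5.9e-15). Its neighbour Ces2e (chromosome 8, 104926260 to 104934672) fell from 73.5 ± 3.79 to 15.3 ± 0.451 CPM, 4.80-fold lower (n = 3; edgeR adjusted p = 7.3e-16). The carboxylesterases are close relatives, and reads that they share could have been divided between them by the counting, so their separate values are uncertain. Fgfbp1 (chromosome 5, 43978858 to 43981779), which encodes a secreted carrier of fibroblast growth factors, was 9.97-fold lower (log2 fold change -3.32 ± 0.102). Elfn2 changed by -2.41, the cell adhesion gene Nectin4 by -2.33, the RNA-binding protein gene Celf5 by -2.15 and Anxa8, an annexin, by -1.97. Notch3, the Notch receptor of smooth muscle cells and pericytes, changed by -1.97, Aldh4a1, a mitochondrial enzyme of proline breakdown, by -1.95, and Cryab, a small heat shock protein gene, by -1.93.

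**Figure D1:**
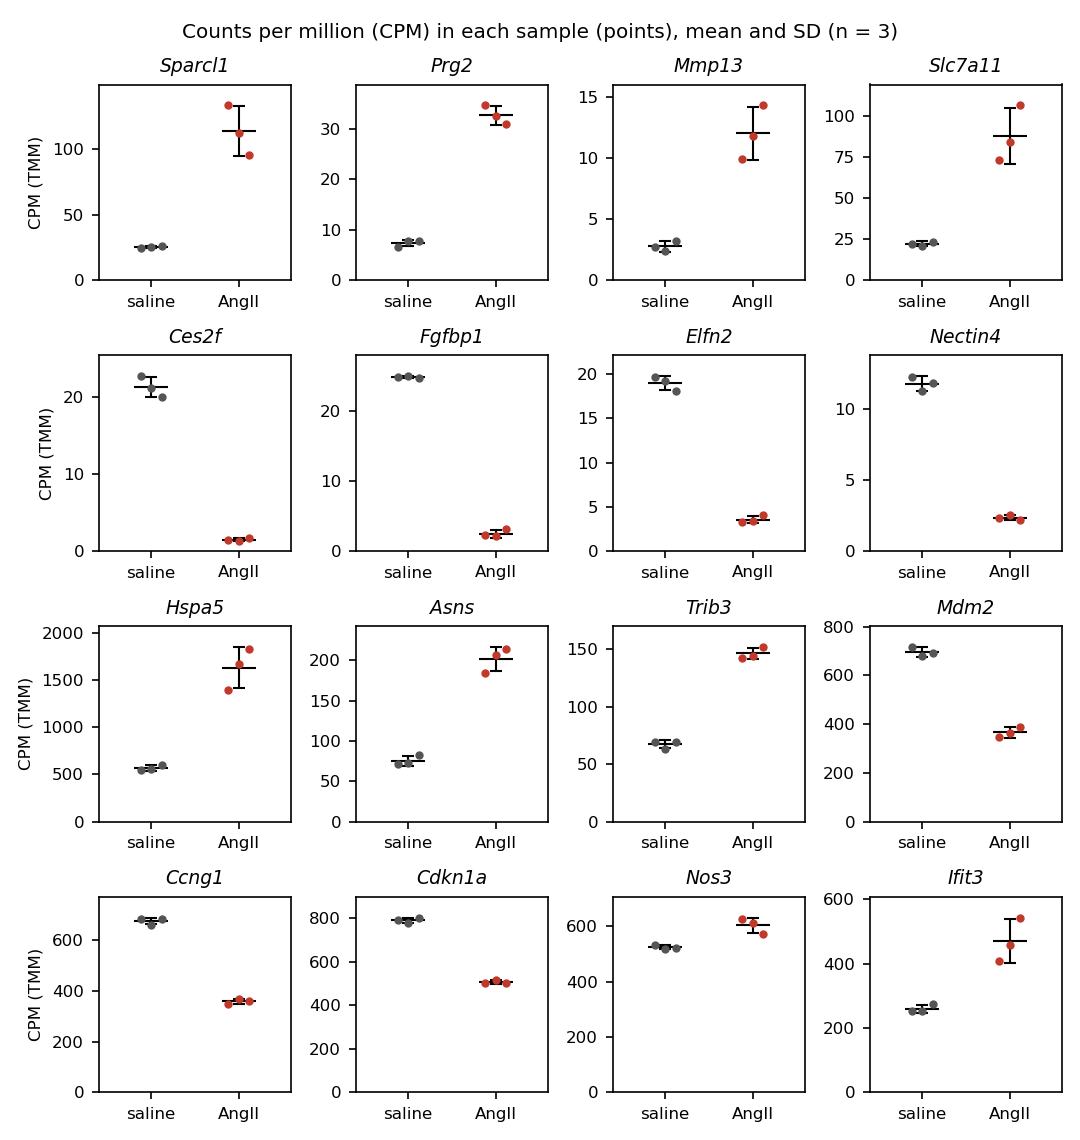
Counts-per-million values (CPM, linear axes from 0) of 16 genes in each of the 3 saline and 3 AngII samples, as points, with the mean (horizontal line) and SD (error bar). The top row shows the 4 largest rises among genes eligible for naming by size (a mean of at least 5 CPM), the next the 4 largest falls among them, and the others genes discussed under their lists, of which Hspa5, Cdkn1a and Ifit3 were chosen after their values were seen. In all 16 genes the samples of the groups do not overlap, which the rule for naming required of the largest rises and falls. Most of the others were named for small p-values or chosen after their values were seen.

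The unfolded protein response and the integrated stress response are linked programmes, the one answering misfolded protein in the endoplasmic reticulum and the other a shortage of amino acids and further stresses. All 22 tested members of this list rose, and the count was also 22 when adjusted over the list alone. Its median log2 fold change was 0.88 (camera adjusted p = 4.5e-37; adjusted p = 0.331 with an estimated correlation). Asns, the asparagine synthetase, rose from 75.3 ± 5.86 to 201 ± 15.1 CPM, Trib3, a pseudokinase target of the same response, was 2.17-fold higher, and Xbp1, a transcription factor of the unfolded protein response, was 2.01-fold higher (n = 3). Hspa5, the main chaperone of the endoplasmic reticulum, was chosen after its values were seen and rose from 569 ± 27.5 to 1633 ± 219 CPM (2.87-fold; edgeR adjusted p = 1.2e-12). The members of this list were strongly correlated within the groups, with an estimated correlation of 0.856.

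Target genes of p53, the transcription factor that responds to DNA damage, were lower on balance. In the p53 and senescence list, 12 of 21 tested members fell and 3 rose, with the same counts adjusted over the list alone, and the median log2 fold change was -0.23 (camera adjusted p = 9.2e-08; adjusted p = 0.207 with an estimated correlation). Mdm2, which encodes the ubiquitin ligase of p53 (chromosome 10, 117688875 to 117710758), fell from 696 ± 19.6 to 367 ± 21.8 CPM. Ccng1 fell from 676 ± 12.8 to 359 ± 10.3 CPM and Ei24 from 225 ± 4.12 to 114 ± 2.09 CPM (n = 3 each). Cdkn1a, the p21 inhibitor of the cell cycle, was chosen after its values were seen and was 1.56-fold lower. Gadd45a, a growth arrest gene that the integrated stress response also induces, rose by 0.56 on the log2 scale. Of the cell cycle list, 17 of 33 tested members rose and 4 fell, with the same counts adjusted over the list alone, and the list did not pass camera (median log2 fold change 0.12, adjusted p = 0.0952). Cenpa (0.37) and Plk1 (0.34), genes of mitosis, rose, while Ube2c (-0.36) and Rrm2 (-0.31) fell.

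Interferon-induced genes, which limit viral replication, were higher with AngII. Of 28 tested members 22 rose and 1 fell, or 23 and 1 adjusted over the list alone, with a median log2 fold change of 0.33 (camera adjusted p = 1.2e-07; adjusted p = 0.638 with an estimated correlation). Ifit3b rose by 0.98 and the guanylate-binding protein gene Gbp3 by 0.72, while Gbp2 changed by -0.17. Ifit3b and Ifit3 are near-identical copies, so the reads assigned to each are uncertain. In the list of leukocyte adhesion and cytokines 12 of 19 members rose and 6 fell, with the same counts adjusted over the list alone, and camera did not pass (median 0.32, adjusted p = 0.108). The chemokine genes Cxcl2 (2.62-fold), Ccl2 (1.74-fold) and Cxcl12 (1.30-fold) were higher, while P-selectin, Selp (1.45-fold), the growth factor Csf1 (log2 fold change -0.32) and E-selectin, Sele (1.21-fold), were lower. The adhesion genes Vcam1 (log2 fold change 0.13, edgeR adjusted p = 0.0052) and Icam1 (0.20, adjusted p = 0.041) were slightly higher. The Icam1 call was lost in DESeq2 (adjusted p = 0.156), with library totals alone (0.0535), without the filter (0.0502) and without any 1 of the 6 samples (0.054 to 0.143). The Vcam1 call was lost once the trend on GC content and length was removed (adjusted p = 0.220).

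Cholesterol synthesis genes rose in 18 of 21 tested members and 1 fell, with the same counts adjusted over the list alone (median log2 fold change 0.39; camera adjusted p = 4.7e-07; adjusted p = 0.616 with an estimated correlation). Msmo1 was 1.57-fold and Hmgcs1 1.41-fold higher, and Mvd was 1.42-fold lower. Fatty acid handling genes were divided, with 10 of 20 higher and 9 lower, also adjusted over the list alone (median 0.20, camera adjusted p = 0.795). The desaturases Scd1 (0.65) and Scd2 (0.46) rose, while Cpt1a (-0.66), which admits fatty acids to mitochondria, Pdk4 (-1.06) and the lipid droplet gene Plin2 (-0.52) fell. Glycolysis genes rose in 6 of 16 and fell in 6, or 6 and 7 adjusted over the list alone, with a median of -0.04, a mean of 0.03 and camera upward (adjusted p = 0.845), and Hk2, a hexokinase, rose by 0.83. Nuclear genes of oxidative phosphorylation fell in 18 of 43 and rose in 6 (median -0.09, camera adjusted p = 0.235), mitochondrially encoded genes fell in 6 of 13 and rose in 1 (median -0.08, adjusted p = 0.576), and hypoxia genes rose in 9 of 17 and fell in 5 (median 0.12, adjusted p = 0.139), all with the same counts adjusted over the list alone. Uqcrq, a subunit of complex III, rose by 0.64, mt-Co1 changed by -0.16, Egln3 by 0.54 and Mxi1 by -0.34.

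Immediate early genes, transcription factors and regulators that respond within minutes to growth factors and stress, rose in 14 of 18 members and fell in 3, also adjusted over the list alone (median log2 fold change 0.39; camera adjusted p = 3.9e-05; adjusted p = 0.307 with an estimated correlation). Egr1 rose from 9.69 ± 0.735 to 29.3 ± 1.23 CPM (n = 3), the phosphatase gene Dusp1 by 0.63 and Atf3, which is also in the stress response list, by 0.76, while Fos (-0.80) and Junb (-0.62) fell. Heat shock genes were mixed, with 3 of 11 higher and 4 lower by either adjustment, over all genes or adjusted over the list alone. Their median was 0.02, their mean -0.06 and camera pointed downward (adjusted p = 0.576). Hsp90ab1, a cytosolic chaperone, rose by 0.27, and Hspb1 (-0.69) and Dnajb1 (-0.44) fell.

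Extracellular matrix genes rose in 14 of 23 members and fell in 3, also adjusted over the list alone (median log2 fold change 0.26; camera adjusted p = 0.0021; adjusted p = 0.638 with an estimated correlation). Bgn, which encodes the proteoglycan biglycan, was 2.38-fold, the collagen crosslinker Loxl2 1.77-fold and tenascin C, Tnc, 1.27-fold higher, while Fbn1, the fibrillin gene, fell by 0.68 on the log2 scale. Angiogenic sprouting genes rose in 11 of 16 and fell in 3, also adjusted over the list alone (median 0.25; camera adjusted p = 0.0029; adjusted p = 0.638 with an estimated correlation). Cxcr4, the receptor of Cxcl12, was 2.49-fold higher (log2 fold change 1.31 ± 0.0406, SE), Pgf was 1.76-fold and Vegfa 1.46-fold higher, and Esm1 was 1.56-fold lower. Pdgfb fell by 0.17 on the log2 scale (edgeR adjusted p = 3.4e-04), a call lost once the trend on GC content and length was removed (adjusted p = 0.204). In the arterial and Notch list 5 of 12 rose and 3 fell (median 0.17, camera adjusted p = 0.188), in the matrix proteases and inhibitors 7 of 15 rose and 7 fell (median 0.06, adjusted p = 0.928), and in the TGF-beta and mesenchymal transition list 10 of 25 rose and 10 fell, all with the same counts adjusted over the list alone. The last had a median and a mean just below 0 (-0.01 each) and an upward camera direction (adjusted p = 0.536). Dll4 and Hes1 (1.99-fold) rose, while Notch1 (1.36-fold), the ligand gene Jag2 (1.51-fold) and Nrarp (log2 fold change -0.16) were lower. Mmp13 and Adamts1 (2.02-fold) rose while the protease inhibitor genes Timp2 (1.52-fold) and Timp3 (1.75-fold) were lower. Tgfb2 (0.87) and Zeb2 (0.84) rose while Bmp4 (-0.37) and Cdh2 (-0.34) fell.

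Antioxidant genes and targets of NRF2, the transcription factor that answers oxidative stress, fell in 13 of 23 members and rose in 3, also adjusted over the list alone (median log2 fold change -0.16; camera adjusted p = 0.0231; adjusted p = 0.653 with an estimated correlation). The quinone reductase gene Nqo1 fell from 70.5 ± 1.48 to 30.3 ± 0.687 CPM (2.33-fold, n = 3), and Gpx1 was 1.75-fold and Gclc 1.43-fold lower. The 3 that rose were Slc7a11 (3.97-fold), Srxn1 (1.83-fold) and Hmox1 (1.10-fold). The list's call was lost without AngII replicate 1 (camera adjusted p = 0.113). Targets of YAP and TEAD, which respond to cell tension, fell in 7 of 13 and rose in 3, also adjusted over the list alone (median -0.10; camera adjusted p = 0.0231; adjusted p = 0.638 with an estimated correlation). Among them the receptor kinase gene Axl was 4.36-fold, Ajuba 1.68-fold and Amotl2 1.53-fold lower, and Amotl1 (1.23-fold) and Ccn2 (1.16-fold) were higher. Ccn2, which encodes a matrix-associated growth factor, and Axl, a receptor of Gas6, are both induced by YAP and went opposite ways.

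**Figure D2:**
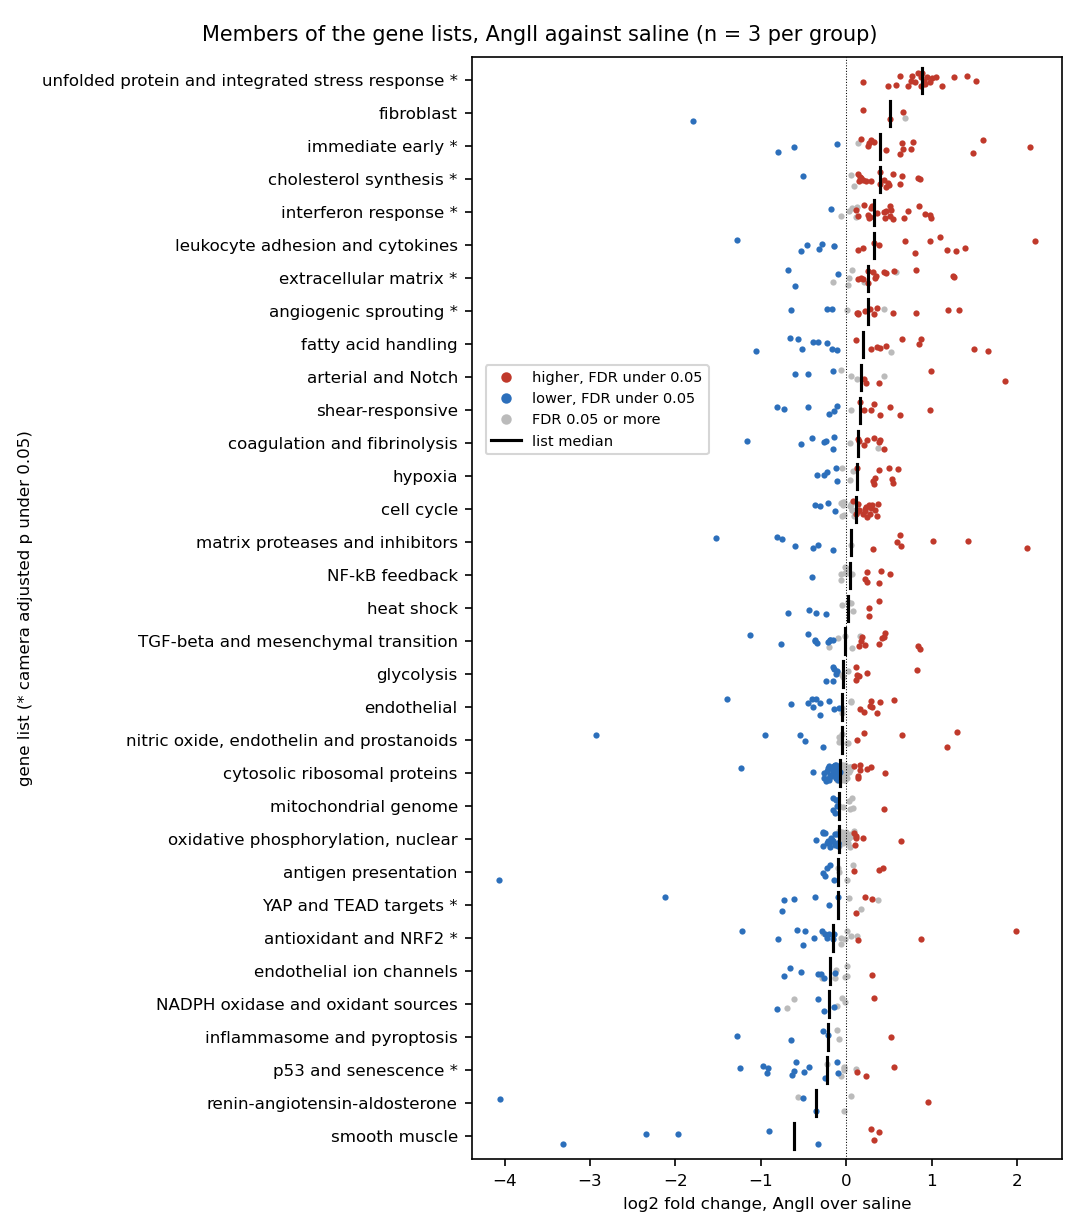
Log2 fold change (AngII over saline, linear axis) of each tested member of the 33 gene lists with at least 5 tested members, 1 point per gene, with a black bar at the list's median. Red and blue points passed an adjusted p of 0.05 in edgeR, higher or lower, and an asterisk marks the 9 lists that passed camera with the preset correlation. The unfolded protein and integrated stress response list sits to the right of 0 with all 22 members, and most other lists hold members on both sides.

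Genes of vessel tone changed in both directions. In the list of nitric oxide, endothelin and prostanoids 5 of 15 rose and 5 fell, also adjusted over the list alone (median log2 fold change -0.05, camera adjusted p = 0.515). Nos3, the endothelial nitric oxide synthase, rose from 524 ± 8.16 to 603 ± 27.1 CPM (1.15-fold, n = 3; edgeR adjusted p = 6.4e-05). The prostaglandin synthase Ptgs2 (2.45-fold) and, at a low level, Nos2 (2.26-fold, 4.255 ± 0.2019 to 9.648 ± 2.045 CPM) were also higher. Edn1, the endothelin 1 gene, was 1.45-fold lower and Ass1, which regenerates the substrate of nitric oxide synthases, 1.93-fold lower. Ptges, a prostaglandin E synthase, was 7.63-fold lower at a low level (3.563 ± 0.4959 to 0.4623 ± 0.01773 CPM). In the renin-angiotensin-aldosterone list 1 of 7 rose and 3 fell (median -0.35, camera adjusted p = 0.235), and in the list of NADPH oxidase and oxidant sources 1 of 10 rose and 4 fell (median -0.21, adjusted p = 0.402), with the same counts adjusted over the list alone. Ace, the angiotensin converting enzyme, was 1.94-fold higher at a low level (2.92 ± 0.511 against 5.64 ± 0.180 CPM, n = 3; edgeR adjusted p = 5.2e-06). Agtrap, which encodes a protein that binds the type 1 receptor of AngII, was 1.42-fold and Lnpep 1.28-fold lower, and the mast cell chymase gene Cma1 went from 1.47 ± 0.195 to 0.0837 ± 0.0393 CPM. Nox4, the main NADPH oxidase of endothelial cells, rose by 0.32 on the log2 scale, and Maoa and Xdh were 1.26-fold and 1.20-fold lower.

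Shear-responsive genes rose in 8 of 15 and fell in 6 (median log2 fold change 0.16, camera adjusted p = 0.928), coagulation and fibrinolysis genes rose in 8 of 17 and fell in 7 (median 0.13, mean -0.01, adjusted p = 0.576), and endothelial ion channel genes rose in 1 of 14 and fell in 7 (median -0.19, adjusted p = 0.0566), with the same counts adjusted over the list alone. Klf2, the transcription factor induced by laminar flow, was 1.65-fold lower and Ptgds rose by 0.98. The fibrinolysis genes Plau (1.31-fold) and Plat (1.30-fold) were higher, Itpr2, a calcium release channel, rose by 0.30, and Stim1 changed by -0.53. Of the NF-kB feedback genes 6 of 14 rose and 1 fell, also adjusted over the list alone (median 0.05, camera adjusted p = 0.212), with Nfkbia (0.51) and Nfkbiz (0.38) higher and Traf1 (-0.40) lower. Of the inflammasome and pyroptosis genes 1 of 7 rose and 4 fell, also adjusted over the list alone (median -0.22, adjusted p = 0.235), with Casp4 (0.53) higher and Txnip (-0.64) lower. Antigen presentation genes rose in 3 of 13 and fell in 6, or 3 and 7 adjusted over the list alone (median -0.10, adjusted p = 0.255), with Psmb8 (0.43) higher and H2-D1 (-0.25) and Tap1 (-0.27) lower. Cytosolic ribosomal protein genes fell in 34 of 75 and rose in 8, or 33 and 8 adjusted over the list alone (median -0.07, adjusted p = 0.0952), with Rps19 changed by -0.39 and Rps27a by 0.45.

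Most markers of endothelial cells were abundant in both groups, while Vwf (10.7 ± 0.140 and 8.12 ± 1.36 CPM with saline and AngII) was low. Pecam1 was 1846 ± 19.3 CPM with saline and 1919 ± 93.4 CPM with AngII (n = 3; log2 fold change 0.06, edgeR adjusted p = 0.195), a difference that passed only without AngII replicate 3 (0.09, adjusted p = 0.0261). Of 23 endothelial markers 8 rose and 11 fell, also adjusted over the list alone (median -0.05, camera adjusted p = 0.237). Cdh5, the endothelial cadherin, was 1.16-fold, Sox7 1.48-fold, Plvap 1.23-fold and S1pr1 1.22-fold higher, while Robo4 (1.56-fold), Podxl (1.36-fold), Mmrn2 (2.63-fold) and Vwf (1.32-fold) were lower. With the trend on GC content and length removed, the log2 fold change of Vwf went from -0.40 to -0.26, that of Notch1 from -0.45 to -0.28 and that of Nos3 from 0.20 to 0.32, with the calls kept.

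Markers of other cell types ranged widely in level, and several fell with AngII. The smooth muscle genes Acta2 (0.180 ± 0.0432 and 0.111 ± 0.0622 CPM with saline and AngII) and Tagln (0.259 ± 0.105 and 0.0843 ± 0.00447 CPM) were below the count filter. Des (1.59 ± 0.260 to 0.152 ± 0.0572 CPM), Myh11 (0.958 ± 0.357 to 0.183 ± 0.0661 CPM) and Notch3 fell. Smtn (log2 fold change 0.32) and Cald1 (0.29), which endothelial cells also express, were higher. Mylk, at 61.85 ± 0.6614 CPM with saline, also fell (-0.33), and Mustn1, at 3.024 ± 0.1704 CPM with saline, rose (0.38). In all, 3 of 8 tested smooth muscle markers rose and 5 fell, also adjusted over the list alone (median log2 fold change -0.62, camera adjusted p = 0.212). Of 4 tested mesothelial or epithelial markers 3 fell, among them Krt7 (3.11 ± 0.586 to 0.391 ± 0.0437 CPM) and Msln (2.47 ± 0.278 to 1.24 ± 0.0473 CPM). Of 5 tested fibroblast markers 3 rose and 1 fell (median 0.51, mean 0.05, camera adjusted p = 0.576), with Pdgfra changed by 0.66 and Serpinf1 by -1.79. Of 4 tested lymphatic endothelial markers 3 rose and 1 fell, with Lyve1 rising from 96.8 ± 1.39 to 187 ± 9.72 CPM. Prox1 (0.090 and 0.055 CPM with saline and AngII), Ccl21a (0 and 0.014 CPM) and Mmrn1 (0 and 0.028 CPM) of that list were below the count filter. So were Dcn (0.16 and 0.18 CPM) and Lum (0.015 and 0 CPM) of the fibroblast list and Plin1 (0.060 and 0.055 CPM) of the adipocyte list. All these genes below the filter were chosen after their values were seen. Of the remaining lists, 1 of 3 macrophage, 1 of 2 lymphocyte (Lck, 0.34), 1 of 1 adipocyte (Fabp4, 0.86) and 1 of 2 Schwann markers rose, none of those tested fell, and 0 erythroid markers were tested. Cd68, of the macrophage list and chosen after its values were seen, was 270 ± 2.05 CPM with saline and 270 ± 8.48 CPM with AngII. Ptprc (0.058 and 0.013 CPM with saline and AngII), Adgre1 (0.060 and 0.014 CPM) and Csf1r (0.015 and 0.042 CPM) were below the count filter. They belong to the same list and were also chosen after their values were seen. For the fibroblast, lymphatic, mesothelial, macrophage, lymphocyte, adipocyte and Schwann lists the counts adjusted over the list alone were the same.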

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

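Tests against a 1.5-fold change and with the GC and length trend removed were chosen after the result was seen, and the others were planned. Without the low-count filter 738 genes at least doubled or halved, of 17053 tested, and with at least 5 CPM in at least 3 samples 181 of 10140, against 482, since the filter decides how many genes of low count enter. Against a fold change of 1.5 in place of none, 252 genes were higher and 356 lower, which a stricter null hypothesis gives by construction. The other alternatives (size factors, library totals, DESeq2, limma-voom, block, GC and length) gave 3014 to 3627 higher and 3010 to 3704 lower genes. Without 1 sample at a time, 3159 to 3487 genes were higher, 3175 to 3520 lower and 507 to 556 at least doubled or halved, and 9 to 12 lists passed. DESeq2 shared 6017 calls with edgeR. With an estimated correlation 0 lists passed camera (3 at an unadjusted p under 0.05, lowest adjusted p = 0.207), while fry, which does not compare a list with other genes, gave 22. The replicate number as a block gave 3627 higher and 3577 lower genes, 484 doubled or halved and 8 lists, the antioxidant list being lost (adjusted p = 0.0579). The correlations of same-numbered samples' deviations were 0.033, -0.14 and 0.095, and not every sample correlated best with its own number, so the numbers were not taken to pair the samples. Among 165 genes followed through the alternatives other than the 1.5-fold test, 160 stayed on their side of the threshold in every fit that tested them (152 were tested at 5 CPM) and 0 changed sign, the exceptions being Icam1, Vcam1, Pdgfb, Pecam1 and Kdm5d. Low counts limit the size filter: below a mean of 5 CPM lay 86 of the 163 doubled and 236 of the 319 halved genes.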

Other observations

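The lists of the next paragraph were drawn up after the result was seen, as were the tests of repeated libraries, shared cultures, handling and smooth muscle cells and the splits for the counts of higher and of lower genes. The tests of GC content and length and of low counts, and the splits for genes changed at least 2-fold and for lists, were written before their results were seen.

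Genes of amino acid transporter families and genes that load amino acids onto transfer RNA were higher on balance with AngII. In a list of 20 genes of amino acid transporter families 13 rose and 2 fell (median log2 fold change 0.48; camera adjusted p over these 8 lists = 4.0e-10; adjusted p = 0.0213 with an estimated correlation). Members were drawn by symbol, so not every one need carry amino acids into the cell. Slc7a1, the arginine and lysine transporter, rose from 232 ± 5.85 to 493 ± 36.1 CPM and Slc1a4 from 19.6 ± 2.08 to 50.3 ± 3.72 CPM (n = 3). Of 20 cytosolic aminoacyl-tRNA synthetases 16 rose and 1, Qars, fell (median 0.52; camera adjusted p = 4.3e-15; adjusted p = 0.132 with an estimated correlation), with Nars 1.99-fold and Eprs 1.88-fold higher. Of 17 mitochondrial synthetases 7 rose and 2 fell (median 0.16; camera adjusted p = 0.148). In serine and folate one-carbon metabolism 7 of 12 rose and 2 fell (median 0.46; camera adjusted p = 2.3e-04; adjusted p = 0.114 with an estimated correlation), with Psph 2.54-fold and Mthfd2 2.29-fold higher and Aldh1l1, the cytosolic relative of Aldh1l2, 2.81-fold lower. Of 31 genes of the endoplasmic reticulum translocon and oligosaccharyltransferase 24 rose and 0 fell (median 0.28; camera adjusted p = 2.4e-12; adjusted p = 0.132 with an estimated correlation), and Rpn1 rose from 87.9 ± 1.66 to 250.3 ± 9.56 CPM and Magt1 from 61.8 ± 0.887 to 135 ± 5.00 CPM. Of 37 proteasome genes 12 rose and 6 fell (median 0.04; camera adjusted p = 0.363).

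More lysosomal genes fell than rose, and most carboxylesterases fell. Of 39 lysosomal enzymes and membrane proteins 19 fell and 6 rose (median log2 fold change -0.09; camera adjusted p = 0.0011; adjusted p = 0.195 with an estimated correlation), among them Man2b1, 2.10-fold lower, and the protease gene Ctsd, which fell from 917 ± 18.9 to 598 ± 18.0 CPM (n = 3). Of 5 carboxylesterases 4 fell (median -1.62; camera adjusted p = 1.1e-16; adjusted p = 0.0076 with an estimated correlation), and Ces2g was 3.07-fold and Ces2b 1.59-fold lower. These lists were chosen on the same samples, the carboxylesterases after Ces2e and Ces2f had stood out, so the tests are not independent evidence of their direction.

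At a common depth of 21154724 counts, 15039.7 ± 26.3 genes had at least 1 count with saline and 14672.7 ± 69.9 with AngII (n = 3; exact permutation test, two-sided p = 0.1, the smallest this design allows). Kdm5d, which lies on the Y chromosome and is the tested member of the sex-linked list, was 2.68 ± 0.463 CPM with saline and 1.99 ± 0.0445 CPM with AngII. The difference passed in edgeR (adjusted p = 0.0377 over all genes and 0.0209 adjusted over the list alone), and the call was lost in DESeq2 (0.125), in limma-voom (0.0548) and without each sample in turn except saline replicate 1 (0.0658 to 0.211).

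In all, 7072 genes passed with 3 samples per group, on a spread between replicates of 3.19%. The 6 samples can be divided into 3 and 3 in 10 splits. In 1 of them, the real one, 3555 genes were higher, 3517 lower and 482 changed at least 2-fold. The other splits gave 0 in edgeR, with at most 164 genes at an unadjusted p under 0.05 against 7574. Each of these other splits holds samples of both groups on each side, so the group difference adds to the spread within sides. Few calls then follow by design, and the 0 calls do not measure chance. For lists, 5 splits gave as many as the real 9 (highest other 11), and 10 splits are too few to exclude chance. Of the 9 lists, 4 had a smaller camera adjusted p in another split than in the real one: interferon (6.85e-12 against 1.2e-07), extracellular matrix (3.0e-04 against 0.0021), sprouting (0.0024 against 0.0029) and antioxidant (0.0025 against 0.0231). Camera also called the unfolded protein and integrated stress response list in 9 of 9 other splits (lowest adjusted p = 1.6e-10). It called cholesterol in 7, interferon in 6, immediate early in 5, and matrix and sprouting in 4 each. The p53 list passed in 3, antioxidant in 2 and YAP and TEAD in 0. Only YAP and TEAD had a larger absolute median in another split (0.1057 against 0.1). The other splits keep part of the group difference, so these calls do not measure chance. One library counted more than once is argued against by the lowest chi-square per degree of freedom between replicates, 2.387. A repeated library gives about 1. A trend on GC content and length as the source of most calls is argued against by the 7042 genes called once it was removed. Of these, 6259 were among the 7072. A trend was present, as log2 fold changes correlated with GC content (Spearman -0.2) and little with length (0.0496). It stays open whether the samples of a group may share a culture or RNA pool: the spread of 3.19% cannot be told apart from that of separate libraries of 1 RNA, because the labels do not name separate animals or cultures. The infusion stays open as the biological explanation.

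The rise of the unfolded protein and integrated stress response list had a median log2 fold change of 0.881 (SD of its members 0.293). A bias of GC content or length is argued against, since the median was 0.908 (SD 0.297) after the trend was removed. A difference in culture or handling between the groups before lysis could also raise these genes, and it cannot be told apart from the infusion, since the labels give no culture batch: the immediate early list rose (median 0.394) and the heat shock list did not (0.0235). The infusion stays open as the biological explanation.

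Genes at least 2-fold lower outnumbered those at least 2-fold higher by 1.96 to 1. A bias of GC content or length is argued against, since the ratio was 1.89 (297 to 157) after the trend was removed. Contractile smooth muscle cells in the saline cultures are argued against by Acta2 at 0.18 ± 0.0432 CPM and Tagln at 0.259 ± 0.105 CPM. These lay below Des at 1.585 ± 0.259 and Myh11 at 0.958 ± 0.357. Whether other cell types were more frequent in the saline cultures was not tested. The tested mesothelial or epithelial markers fell in 3 of 4 and rose in 0, and the fibroblast markers rose in 3 of 5 and fell in 1. The excess lay among genes of low level, as the ratio was 1.08 (83 to 77) at a mean of at least 5 CPM and 2.74 (236 to 86) below. Low counts stay a candidate explanation, but these ratios show where the excess lies and not why falls outnumber rises there. Whether the infusion removed transcripts of low level, as the count of detected genes could also reflect, was not tested.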
